A study of Homo sapiens with 11 samples.

How the data were processed

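ZFP36L2 binding was measured by eCLIP in the human acute monocytic leukaemia lines MOLM13 and THP1. Per the labels' protocols, cells were crosslinked at 254 nm with 400 mJ/cm2, lysates were immunoprecipitated with an antibody to ZFP36L2 or with control IgG, and material of 30 to 105 kDa was taken from the membrane. The input is 2% of the lysate taken before immunoprecipitation and carried through the same size selection. The 11 libraries comprised 2 immunoprecipitates and 2 IgG libraries per line, 2 MOLM13 inputs and 1 THP1 input. Groups and replicate numbers were taken from the labels.

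The submitters' processing notes name cutadapt 1.14, STAR 2.5.0c, Picard 2.6.0 and edgeR, and the builds hg19, GRCh37 and hg38, without saying which served for which step. The peak caller and the read depth per library are not given in the sources used here, and all files used here carry hg38 contig names. The deposited files hold comparisons made by the authors per immunoprecipitate, so clusters were called in each replicate by itself and not on pooled samples. In the 4 deposited IgG lists the authors give, for every cluster, the −log10 p and the log2 fold of the immunoprecipitate over IgG. In the 4 deposited input tables the authors give the same values over input together with gene name, Ensembl identifier and region, for peaks with a log2 fold of at least 3 and a −log10 p of at least 3 only, as the smallest values in each table showed. The −log10 p of the authors is capped at 400, and in the IgG lists it is 0 for clusters below the control. The test behind that p and the scaling of the fold are not given in the sources used here. It is also not stated whether both THP1 folds over input rest on the same input library, in which case part of the overlap between THP1 replicates can come from that library. The IgG lists were tied to the input tables of the same immunoprecipitate by identical cluster coordinates, since the THP1 lists are numbered differently.

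Neighbouring peaks often touch, so a count of peaks is higher than a count of binding regions, and 14432, 14425, 19325 and 18901 peaks make 11506, 10461, 14505 and 13950 regions once touching peaks are merged. The median log2 fold over IgG of all clusters was 0.28 and −0.60 in the MOLM13 replicates and 0.0019 and 0.38 in THP1, so an IgG threshold is harder to reach in MOLM13 replicate 2 than in the other libraries. The depth per library is unknown, and intervals printed are Wilson or odds ratio intervals at 95% that cover counting error only. Per-peak folds were used to describe, rank and filter peaks within a list, and no difference of folds between lines was tested.

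Enriched means a log2 fold of at least 3 and a −log10 p of at least 3. A peak of replicate 1 was reproducible when an enriched peak of replicate 2 shared at least 1 base on the same strand, and 100 seeded shuffles of the enriched labels among the clusters of replicate 2 gave the overlap of random lists. A gene was a target of a line when each replicate had an enriched peak over input with its name. Of 6554 gene symbols, 6261 matched a symbol of the RefSeq table of GRCh38.p14, 187 of them as an older symbol, and 98.2% of the 64218 peaks so named lay inside that gene. Current symbols are printed, so that COL4A3BP, SOGA1, TMEM173 and HIST1H3E of the tables appear as CERT1, MTCL2, STING1 and H3C6. Clusters over IgG carry no gene name in the lists and were assigned by the RefSeq coordinates of the same build. The background of a gene test was every gene with a cluster in both replicates of a line, 13814 in MOLM13 and 14402 in THP1, or in all 4 immunoprecipitates for shared targets. Targets outside it were left out of the tests, which used 4047 of 4067 targets in MOLM13 and 4673 of 4691 in THP1. Genes whose names matched no RefSeq symbol, the mitochondrially encoded mRNAs among them, are not counted as targets.

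The tests, thresholds, 19 gene lists, alternatives and the rule for named genes were set before the data were examined, except where the text says otherwise. Lists were tested with two-sided Fisher's exact tests, Benjamini-Hochberg adjusted over 38 tests, and against 10000 random lists with the same number of genes in each of 20 bins of clusters per gene. The lists were the TIS11 family, reported ZFP36-family targets, immediate early genes, cytokines with the NF-kB pathway, myeloid transcription factors, myeloid maturation markers, the HOXA programme, apoptosis and cell cycle regulators, signalling feedback, mRNA decay, other regulators of AU-rich mRNAs, hypoxia and metabolism, lymphoid markers, erythroid and megakaryocytic markers, ribosomal proteins, histones, mitochondrial mRNAs, and small structural RNAs. Named genes were the TIS11 family, the 10 genes per line and the 10 over both lines with the highest 3' UTR peak by the lower replicate's log2 fold over input, up to 4 targets of both lines per list (up to 2 of either line where a list had none), and up to 8 genes per line enriched there with clusters but no enriched peak in the other. This rule gave 76 genes, not all of which are reported here.

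The planned comparison of regions with clusters that are not enriched could not be made, because clusters that are not enriched carry no annotation, and 3' UTR peaks were set against intronic peaks by their enrichment over IgG in its place. The planned search for AU-rich heptamers needs the genome sequence, which was not used here. Alternatives comprised a stricter p, looser and stricter folds, a reciprocal overlap of 50%, IgG in place of input, 3' UTR peaks alone, matched lists, merged touching peaks and each replicate by itself.

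Computations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap and list steps were tested on simulated data. The overlap step recovered 100% of 5000 simulated pairs. Of 100 simulated lists of 30 genes with odds of 6, Fisher's exact test called 92% and matching 96% at a p under 0.05, and 3% and 1% of lists drawn at random. Lists drawn only from genes with many clusters were called in 82% of cases by Fisher's exact test and in 3% with matching, so the matched result is given beside each Fisher call.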

Results

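ZFP36L2 is an RNA-binding zinc finger protein of the TIS11 family, whose members bind AU-rich elements in 3' UTRs and promote decay of the mRNA. The study asked which RNAs ZFP36L2 occupies in acute myeloid leukaemia cells, in connection with the control of their differentiation. Binding was mapped by enhanced crosslinking and immunoprecipitation (eCLIP), in which proteins are crosslinked to RNA by ultraviolet light, the protein of interest is immunoprecipitated and the bound fragments are sequenced. MOLM13 and THP1, established human lines of acute monocytic leukaemia, were used. Each line had 2 immunoprecipitates with an antibody to ZFP36L2 and 2 with control IgG. MOLM13 had 2 size-matched input libraries and THP1 had 1, which makes 11 libraries. Nothing in the labels says that duplicates came from separate cultures, so the spread between duplicates may be technical. The p-values below come from tests across peaks or genes within these libraries and do not measure the spread between cultures.

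The deposited lists held 140287 and 182486 clusters for MOLM13 replicates 1 and 2, and 153162 and 143910 for THP1. Of the peaks scored against input, 14432 and 14425 passed the thresholds in MOLM13 and 19325 and 18901 in THP1 (log2 fold of at least 3 and −log10 p of at least 3). Against IgG, 7165 and 4551 clusters passed the same thresholds in MOLM13 and 8786 and 12038 in THP1. The read depth behind these lists is not given in the sources used here. Fold and −log10 p per peak are the values of the authors' deposited tables, and are given for replicate 1 and then replicate 2. Coordinates are 1-based on hg38 and belong to the replicate 1 peak. A gene's values in the 2 lines can come from peaks at different sites, as for UBE2W, TRIM66 and AGO2.

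ZFP36L2 bound the 3' UTR of its own mRNA in both lines. At chromosome 2, 43223430 to 43223534, the log2 fold over input in MOLM13 was 6.54 and 7.81, and over IgG 4.21 and 4.04. In THP1 the peak at 43223430 to 43223455 reached 6.94 and 7.57 over input and 5.85 and 6.83 over IgG. The mRNA of the paralogue ZFP36 was bound in its 3' UTR at chromosome 19, 39409188 to 39409229, with log2 folds over input of 7.81 and 7.0 in MOLM13 and 7.01 and 7.39 at the overlapping THP1 peak. ZFP36L1 carried an enriched 3' UTR peak in both THP1 replicates, with 4.73 and 4.12 over input, and no reproducible one in MOLM13.

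The strongest 3' UTR peaks of MOLM13 lay on CISH and PIM1. CISH, an inhibitor of STAT signalling downstream of cytokine receptors, had log2 folds over input of 9.60 and 10.44 (chromosome 3, 50607065 to 50607083), followed by the kinase PIM1 with 8.97 and 9.98 (chromosome 6, 37175020 to 37175056). TRIB1, a pseudokinase that directs CEBPA to degradation, had 8.43 and 7.98 (chromosome 8, 125437740 to 125437745). The same genes were bound in THP1, with 6.78 and 6.65 for CISH, 6.21 and 6.30 for PIM1 and 7.04 and 5.83 for TRIB1. Over IgG, CISH reached 5.03 and 5.84 in MOLM13 and 1.84 and 3.77 in THP1, and PIM1 reached 5.88 and 6.04 in MOLM13 and 2.16 and 3.62 in THP1, so replicate 1 of THP1 missed the IgG threshold for both genes. STING1, the adaptor of cytosolic DNA sensing, was bound in MOLM13 with 7.68 and 8.55 over input and 7.11 and 6.61 over IgG (chromosome 5, 139476080 to 139476116). The top 10 of MOLM13 also held UBE2W, CERT1, MTCL2, NSD2, POLR3K and DLG4.

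In THP1 the strongest 3' UTR peaks included the inflammatory mediators IL1B and CXCL8. IL1B had log2 folds over input of 9.25 and 7.94 (chromosome 2, 112829929 to 112830008), and 5.42 and 6.93 over IgG. Its 3' UTR was also a target in MOLM13, with a mean log2 fold over input of 4.13 (SD 0.021 between replicates). CXCL8, a neutrophil chemokine, had 9.15 and 7.72 over input and 6.58 and 5.82 over IgG (chromosome 4, 73743128 to 73743138). In MOLM13 CXCL8 passed over input with 4.89 and 5.15, but its log2 fold over IgG was 0.91 in replicate 1 and −0.29 in replicate 2. VEGFA, the angiogenic growth factor, reached 7.59 and 7.57 over input in THP1 and 7.03 and 7.13 in MOLM13. The others of the THP1 top 10 were DLG4 (9.88 and 8.72), the ceramide transfer protein gene CERT1 (9.41 and 9.68), MTCL2 (9.38 and 8.59), the histone methyltransferase gene NSD2 (8.74 and 8.97), ONECUT2 (8.61 and 8.72), UBE2W (7.81 and 7.98) and HOOK3 (7.75 and 8.43). CERT1, MTCL2, NSD2, DLG4, UBE2W and HOOK3 were also among the 10 genes with the highest fold over all 4 immunoprecipitates, together with STING1, ASB1, DNAJC16 and TRIM66. The last 3 had log2 folds over input between 7.07 for DNAJC16 in MOLM13 replicate 2 and 7.84 for ASB1 in MOLM13 replicate 2. Over IgG, NSD2 (3.48 and 2.55), MTCL2 (4.10 and 2.64), HOOK3 (3.61 and 2.77) and DNAJC16 (3.36 and 2.72) missed the threshold in replicate 2 of MOLM13, and TRIM66 in replicate 1 of THP1 (2.82 and 4.11).

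**Figure D1:**
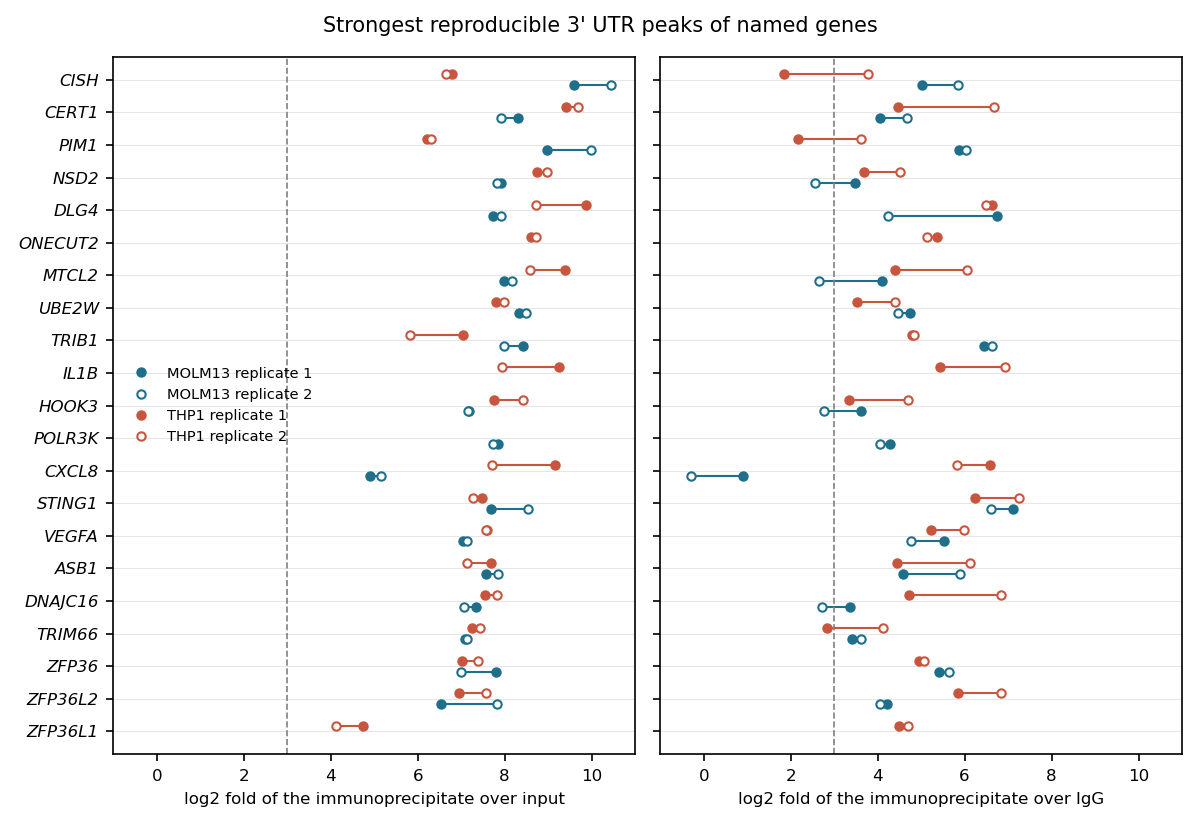
Log2 fold of the ZFP36L2 immunoprecipitate over input (left) and over IgG (right) at the best reproducible 3' UTR peak of 21 named genes, with filled points for replicate 1, open points for replicate 2, lines joining the replicates and a dashed line at the threshold of 3. All plotted folds over input lie between 4.12 and 10.44, whereas CXCL8 in MOLM13 falls to −0.29 over IgG. IL1B is plotted for THP1 only, although its 3' UTR was also a target in MOLM13.

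The 2 replicates of each line shared most of their peaks over input. In MOLM13, 11310 of the 14432 peaks of replicate 1 (78.4%) overlapped a peak of replicate 2 on the same strand, against a mean of 1441 when replicate 2 peaks were drawn at random from its clusters in 100 shuffles. In THP1, 15812 of 19325 (81.8%) overlapped, against 3141. Log2 folds over input of overlapping peaks correlated between replicates, with r = 0.749 and rho = 0.687 in MOLM13 and r = 0.772 and rho = 0.708 in THP1. These are correlations across peaks, which are not independent replicates, within lists that hold only peaks past the threshold. The SD of the difference in log2 fold between replicates was 0.90 in MOLM13 and 0.89 in THP1. Only pairs past the threshold in both replicates enter it, so larger drops are left out and the spread is understated. A smaller difference between lines in a single gene is not told apart from this spread, and larger ones were not tested.

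Enrichment over IgG was reproduced less evenly. In MOLM13, 3385 of the 7165 enriched clusters of replicate 1 (47.2%) and 3574 of the 4551 of replicate 2 (78.5%) overlapped the other replicate. In THP1 the shares were 85.7% and 66.6%. Of the reproducible input peaks, 3088 of 11310 in MOLM13 (27.3%, Wilson 95% interval 26.5 to 28.1) and 7122 of 15812 in THP1 (45%, 44.3 to 45.8) were also enriched over IgG in both replicates. For clusters not enriched over input these shares were 0.140% and 0.183%. The intervals cover counting error only, and both controls were set against the same immunoprecipitates.

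Most reproducible peaks lay in introns and the next largest group in 3' UTRs, per the annotation in the authors' deposited tables. Introns held 73.8% ± 0.89 (SD, n = 2) of the MOLM13 peaks and 79.6% ± 0.13 (SD, n = 2) of the THP1 peaks. 3' UTRs held 19.8% ± 0.83 (SD, n = 2) in MOLM13 and 15.1% ± 0.16 (SD, n = 2) in THP1, coding sequence 3.22% and 2.70%, and 5' UTRs 0.590% and 0.442%. Reproducible peaks of the 2 replicates overlap by definition, so their shares are not independent and these SDs understate the spread. Among all input-enriched peaks, the SD of the 3' UTR share was 1.83 in MOLM13 and 0.42 in THP1. Among peaks with a log2 fold of at least 6 over input, the 3' UTR share was 11.6% ± 2.61 in MOLM13 and 7.91% ± 0.43 in THP1 (SD, n = 2 each). Reproducible peaks also enriched over IgG in their own replicate, whatever the other replicate showed, numbered 6090 and 3808 in MOLM13. Their 3' UTR share was 25.2% and 38.6%. In THP1, where they numbered 7990 and 10757, it was 18.2% ± 1.39 (SD, n = 2). Differences between the lines were not tested.

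**Figure D2:**
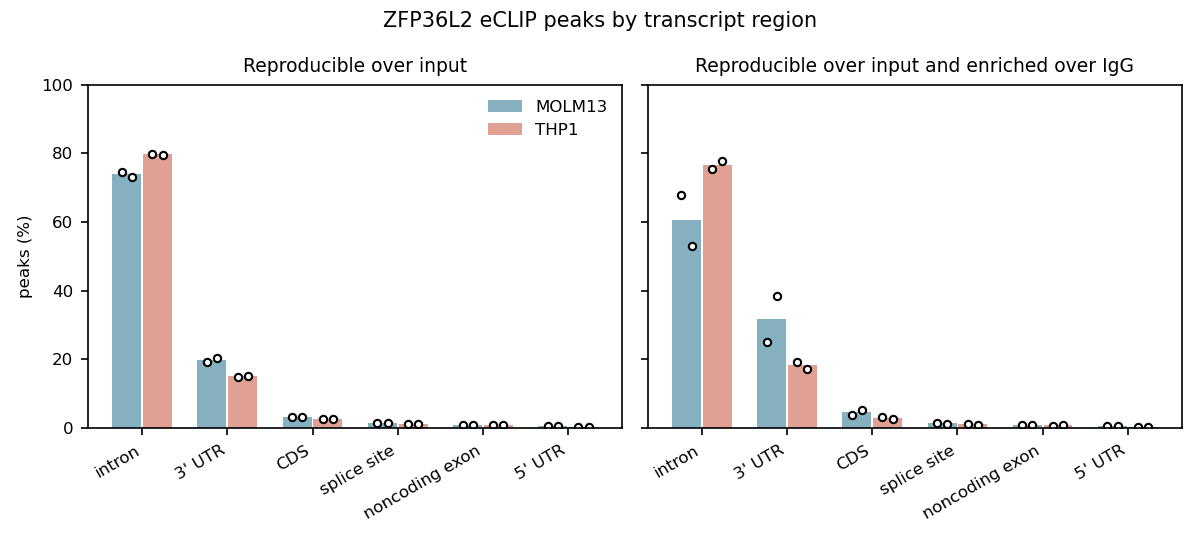
Share of peaks by transcript region (bars, mean of 2 replicates, circles, each replicate, in percent of peaks) for MOLM13 and THP1. Left, peaks reproducible over input, and right, those also enriched over IgG in their own replicate. Introns hold 73.8% and 79.6% of the reproducible peaks and 3' UTRs 19.8% and 15.1%, and the MOLM13 replicates stand apart at 25.2% and 38.6% for 3' UTRs on the right.

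Peaks in 3' UTRs passed the IgG control more often than intronic peaks in all 4 immunoprecipitates. In MOLM13, 59.0% and 49.7% of the 3' UTR peaks over input were also enriched over IgG, against 40.9% and 20.5% of the intronic peaks (odds ratios 2.07 and 3.83, two-sided Fisher's exact test, p = 1.06e-66 and 3.69e-216). In THP1 the shares were 54.6% and 65.1% against 41.0% and 58.8% (odds ratios 1.73 and 1.31, two-sided Fisher's exact test, p = 9.56e-44 and 4.02e-11). Over input the order was the other way round, with median log2 folds of 3.97 and 4.04 in 3' UTRs and 4.57 and 4.48 in introns of MOLM13, and 4.05 and 4.02 against 4.64 and 4.63 in THP1. Position was compared in protein-coding genes longer than 10000 bases that named an enriched peak over input in at least 1 library. Only clusters lying in 1 gene were used. Those enriched over IgG lay within 2000 bases of the gene's 3' end in 18.8% and 27.1% of cases in MOLM13 and 13.2% and 12.6% in THP1. Of all other clusters 9.32%, 8.39%, 8.83% and 8.90% did (odds ratios 2.25 and 4.07, and 1.56 and 1.47). These tests were chosen after the data were seen, treat peaks as independent, and describe these libraries.

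Over input, the lines shared most target genes. With a target defined as a gene with an enriched peak over input in both replicates, 4067 genes were targets in MOLM13 and 4691 in THP1. Among the 12269 genes with clusters in all 4 immunoprecipitates, 3556 were targets of both lines, out of 4020 and 4488, where independent lists would share 1471 and lists matched within 20 bins of clusters per gene 2225. The odds ratio was 60.2 (95% interval 53.4 to 67.9). With 3' UTR peaks alone, 1034 genes were shared out of 1415 and 1463, with 169 for independent and 209 for matched lists. With IgG as the control 1716 genes were shared, 79.6% of the 2155 targets in MOLM13 but 49.7% of the 3450 in THP1, and the odds ratio was 18.9. Targets over IgG were assigned by coordinates and not by name, so this setting differs in more than the control. Genes transcribed at similar levels in both lines can give more overlap than independent lists by themselves. How much of this the matching removes was not tested.

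A minority of genes had enriched peaks in 1 line and none in the other although clusters were listed there. Of 1366 protein-coding genes with a reproducible 3' UTR peak in MOLM13, 91 were of this kind, led by the tyrosine phosphatase gene PTPN3 with log2 folds over input of 7.02 and 6.67 and over IgG of 6.77 and 7.64. By the lower replicate, the activin subunit gene INHBA (5.40 and 5.87), HAGH, TIMM10, the oncogene MYC (5.24 and 4.79, chromosome 8, 127741329 to 127741349), RUSC1, TBX3 and SAMSN1 followed. Of these, TIMM10, RUSC1, TBX3 and SAMSN1 missed the IgG threshold in at least 1 replicate. Of 1442 such genes in THP1, 109 had clusters and no enriched peak in MOLM13. The chromodomain gene CDYL2 (7.07 and 6.39), GPSM1 (7.35 and 6.49), PHLDA1 (6.12 and 5.75) and the metalloproteinase inhibitor gene TIMP3 (5.93 and 6.59) were the highest of these, with MAPRE3, TMCC2, CST3 and ZNF605, of which TMCC2 missed the IgG threshold. Whether any of these differs between the lines was not tested.

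Gene lists fixed beforehand were compared with the other genes of each line. mRNAs reported as ZFP36-family targets were enriched in both lines, with 19 of 24 measured members bound in MOLM13 and 22 of 27 in THP1 (odds ratios 9.21 and 9.20, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 38 tests, adjusted p = 3.82e-06 and 2.06e-06). FOS, PIM1, PIM3 and VEGFA headed this list. For the activator protein subunit gene FOS, log2 folds over input were 7.13 and 7.41 in MOLM13 and 6.91 and 6.40 in THP1, and for the kinase gene PIM3 6.73 and 6.82, and 7.06 and 6.63. Cell cycle regulators were enriched, with 24 of 34 and 18 of 33 bound (adjusted p = 4.10e-06 and 0.0187), among them PLK3 (6.18 and 7.29, and 7.08 and 7.15), CCNG2, E2F1 and CDKN1B. Signalling feedback genes were enriched as well, with 19 of 32 and 22 of 27 (adjusted p = 0.00187 and 2.06e-06), including DUSP1 (5.14 and 5.08, and 4.99 and 4.51), SMAD6, CISH and TRIB1. Bound means enriched over input in these counts. Of these genes, PIM1, CISH, E2F1 and CDKN1B in THP1, DUSP1 in MOLM13 and SMAD6 in both lines missed the IgG threshold in at least 1 replicate. The reported targets counted in MOLM13 also include CXCL2 (1.70 and 2.18 over IgG) and CXCL8 (0.91 and −0.29 over IgG). These 3 lists stayed enriched in both lines against random lists matched on clusters per gene, with 2.57 and 2.71 times the matched mean for the reported targets, 2.12 and 1.61 times for cell cycle regulators and 1.86 and 1.65 times for feedback genes.

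Matching mattered because genes with many clusters are targets more often. Of the 16 calls of enrichment by Fisher's exact test, 6 remained with matched lists. Myeloid transcription factors (16 of 29 and 16 of 30), the HOXA programme and stemness genes (16 of 25 and 14 of 24), mRNA decay factors (23 of 37 and 26 of 37), other regulators of AU-rich mRNAs (13 of 22 and 15 of 23) and hypoxia and metabolism genes (13 of 23 in each line) had been called in both lines and lost the call. Their matched adjusted p was 0.357 and 0.823, 0.941 and 1, 0.285 and 0.0874, 1 and 0.903, and 0.231 and 0.823 in MOLM13 and THP1. Immediate early genes, with 12 of 24 and 14 of 27 bound, went the other way, from an adjusted p of 0.0611 in both lines to 0.000844 with matching, at 3.26 and 2.82 times the matched mean. Cytokine, chemokine and NF-kB genes (9 of 22 and 10 of 26) were called with matching in MOLM13 (adjusted p = 0.0133) but not in THP1 (0.154). The MOLM13 count includes CXCL2 and CXCL8, which missed the IgG threshold in both replicates of that line. The TIS11 family (2 of 3 and 3 of 3), myeloid maturation markers (5 of 22 and 11 of 26) and apoptosis regulators (11 of 24 and 12 of 23) were called by neither test.

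Restricted to 3' UTR peaks and matched on clusters per gene, more lists were enriched. The reported targets held 19 of 24 and 21 of 27 members, 7.31 and 7.64 times the matched mean, and immediate early genes 12 of 24 and 12 of 27, 6.37 and 6.17 times (adjusted p = 0.00076 in each case, from the smallest p that 10000 random lists can give). Cytokine, chemokine and NF-kB genes held 8 of 22 and 9 of 26 (adjusted p = 0.00076 and 0.00138), among them CXCL2 (4.68 and 4.54 in MOLM13, 7.01 and 6.87 in THP1), NFKBIA (5.36 and 5.41, and 5.68 and 5.22) and TGFB1. Myeloid transcription factors held 11 of 29 and 11 of 30 (adjusted p = 0.00557 and 0.00626). In this group FOSL2 had 4.85 and 6.09 over input in MOLM13 and 6.01 and 8.36 in THP1, ZEB2 had 5.39 and 5.87, and 7.60 and 6.44, CEBPD 5.65 and 5.20, and 5.22 and 5.11, and IRF8, a regulator of monocyte development, 5.18 and 5.23, and 5.30 and 5.51. Hypoxia and metabolism genes held 11 of 23 and 10 of 23 (adjusted p = 0.00076 and 0.00557), including VEGFA, the amino acid transporter gene SLC7A5 and the glycolytic regulator gene PFKFB3, which had 6.83 and 5.91 in MOLM13 and 7.58 and 7.36 in THP1. Cell cycle regulators held 18 of 34 and 9 of 33 (adjusted p = 0.00076 and 0.0439) and feedback genes 10 of 32 and 14 of 27 (adjusted p = 0.00526 and 0.00076). CXCL2 and the likewise counted CXCL8 in MOLM13, and TGFB1 in THP1, missed the IgG threshold. This combination of choices was made after the data were seen.

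Other lists were called in a single line or in neither under the 3' UTR restriction with matching. Apoptosis regulators, with BCL2 (4.62 and 4.74 in MOLM13, 4.85 and 5.15 in THP1), BCL2L11, CFLAR and PMAIP1 bound in both lines, held 9 of 24 and 5 of 23 (adjusted p = 0.0038 and 0.398). mRNA decay factors held 11 of 37 and 12 of 37 (adjusted p = 0.074 and 0.0476), among them AGO2, CNOT6L, TNRC6B and UPF1 (4.41 and 5.42, and 5.04 and 5.65). The HOXA programme and stemness genes held 9 of 25 and 7 of 24 (adjusted p = 0.066 and 0.285), with DOT1L (5.24 and 5.45, and 4.52 and 5.41), SATB1, CDK6 and BMI1. Other regulators of AU-rich mRNAs held 3 of 22 and 8 of 23 (adjusted p = 1 and 0.104), including ELAVL1, which stabilises AU-rich mRNAs, with 4.99 and 6.13, and 6.61 and 6.51. The TIS11 family held 2 of 3 and 3 of 3 (adjusted p = 0.104 and 0.00626). Myeloid maturation markers held 1 of 22 and 3 of 26 (adjusted p = 1 in both lines), with SIRPA bound in both at 4.91 and 3.39, and 3.25 and 3.25. Over IgG, SIRPA missed the threshold in both lines, AGO2, CNOT6L, BMI1 and PMAIP1 in THP1, and TNRC6B in MOLM13, and CFLAR had no value over IgG in MOLM13 replicate 1. The difference between lines was not tested for any list.

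Ribosomal protein genes were depleted among targets, and the list of small and structural RNA genes was also called depleted. Of the ribosomal protein genes, 11 of 79 were targets in MOLM13 and 9 of 78 in THP1, 0.435 and 0.332 times the matched mean (matched adjusted p = 0.00138 and 0.000844). With 3' UTR peaks alone this call ended. Then 3 of 79 and 3 of 78 were targets, 0.332 and 0.343 times a matched mean of only 9.04 and 8.74 (matched adjusted p = 0.0642 and 0.0655). The list of small and structural RNA genes kept its call. RPL14 and RPS27L were the exceptions with 3' UTR peaks in both lines, and RPS27L had 7.61 and 6.31 over input in MOLM13 and 6.21 and 5.82 in THP1. None of 315 and 294 small and structural RNA genes of the background was a target, where matched lists gave 25.2 and 31.0. Genes entered the background by coordinates, whereas a target needs its name on the authors' peak. A small RNA gene inside a host gene can be in the background while its peaks carry the host's name. This call can therefore come from the naming and does not show absence of binding. RNU1-124P of this list was a target in MOLM13 by the name in the tables (3.54 and 4.46 over input), but the peak centre lay outside its RefSeq coordinates, so it was not in the background. Histone genes, with 4 of 46 and 1 of 46, were depleted by Fisher's exact test (adjusted p = 0.00302 and 3.82e-06) but not with matching (adjusted p = 1 and 0.228), and the MOLM13 targets included H3C6 with 3.49 and 4.08 over input. Markers of other blood lineages gave little to count, with 1 of 2 and 1 of 1 measured lymphoid genes and 2 of 2 and 1 of 3 measured erythroid or megakaryocytic genes bound, and neither list was called. The transferrin receptor gene TFRC of the latter list had 3' UTR peaks in both lines, at 4.01 and 5.12, and 3.66 and 3.80. Over IgG, RPL14 missed the threshold in both lines, RPS27L and H3C6 in MOLM13 and TFRC in THP1. The list of mitochondrially encoded mRNAs was not tested, because their names matched no RefSeq symbol. By the names in the tables, MT-ND1, MT-ND2 and MT-ND6 had peaks over input in both replicates of both lines, and MT-ND3 and MT-ND4 in both of THP1. MT-ND2 was the highest, with 4.19 and 4.23 in MOLM13 and 5.29 and 5.30 in THP1, where it was also enriched over IgG (3.27 and 4.28). None of the other mitochondrial mRNAs had a peak enriched over IgG, and all MT-ND6 peaks of THP1 and of MOLM13 replicate 2 lay at or below IgG.

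**Figure D3:**
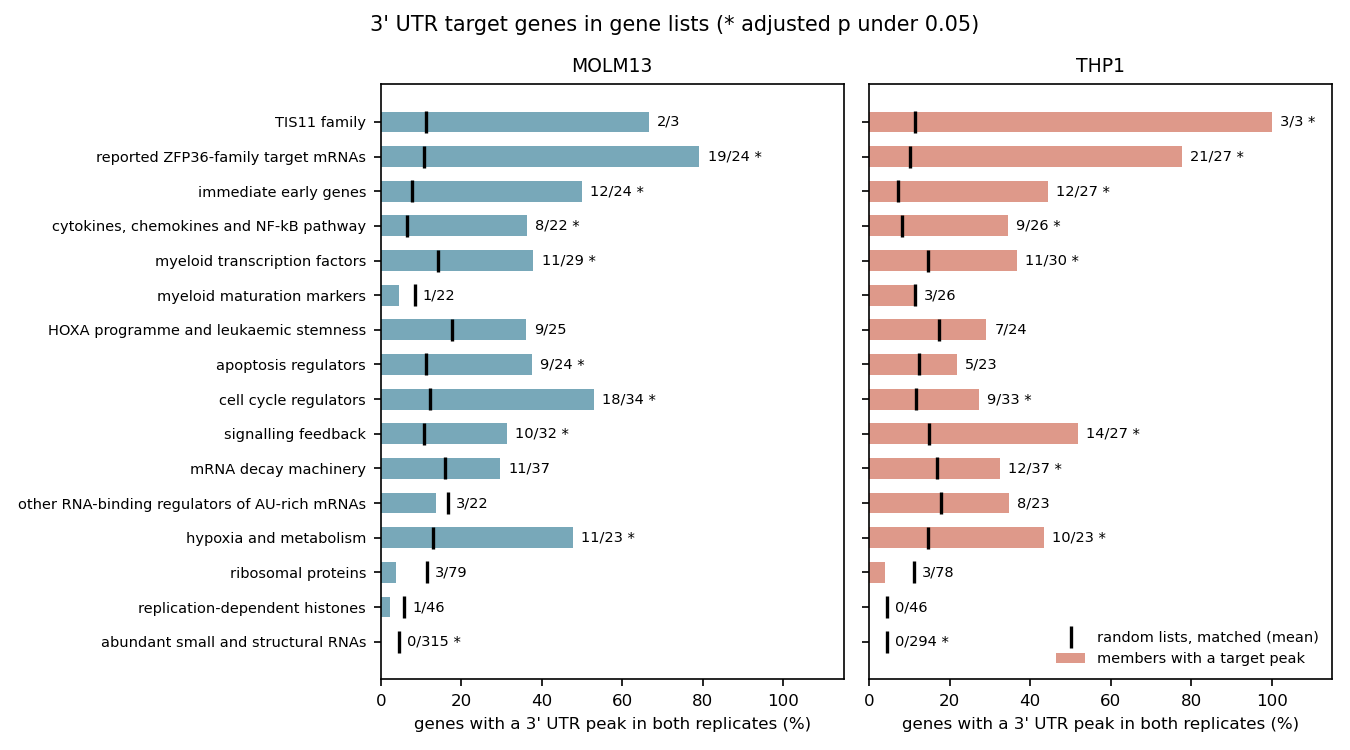
Percent of the measured genes of each list with an enriched 3' UTR peak in both replicates (bars, with counts) in MOLM13 and THP1, beside the mean of random lists matched on clusters per gene (black ticks), with asterisks at an adjusted p under 0.05. The reported ZFP36-family targets reach 19 of 24 in MOLM13 and 21 of 27 in THP1. None of the 315 and 294 small and structural RNA genes is named by such a peak, though peaks inside a host gene can carry the host's name.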

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

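The bound of 2 on the log2 fold and the test in genes with few MOLM13 clusters were chosen after the result was seen. Signs of the fold over IgG were compared between the lines across 43422 regions with a cluster in all 4 immunoprecipitates. In 629 regions both MOLM13 replicates lay above IgG and both THP1 replicates below, and in 846 regions the reverse held. Independent lines would give 2895 and 2949, so fully opposite regions were fewer than that. The difference between the lines was not tested for any of these regions.

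With log2 folds beyond 2 in all 4 libraries, 4 regions remained, all in introns and all above IgG in THP1 and below it in MOLM13. Independent lines would give 55.7 regions of this kind and 145 of the reverse kind, so these too were fewer than that. Their higher MOLM13 value was −3.42 and −2.56 at FAM135B (chromosome 8, 138314628 to 138314713 and 138433452 to 138433538), −4.11 at NAV3 (chromosome 12, 78140895 to 78141027) and −3.04 at ZNF254 (chromosome 19, 24088634 to 24088720). In THP1 the sites reached 4.99 and 5.88, 4.66 and 7.14, 3.04 and 5.69, and 4.72 and 5.76 over IgG in the 2 replicates, and between 6.23 and 9.79 over input. These differences between the lines were not tested.

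For these 4 sites, equal transcription of the genes in both lines was judged by their clusters elsewhere. MOLM13 held 0.316% of the THP1 number (2 against 632), which argues against equal recovery of these RNAs in the immunoprecipitates. Such clusters depend on binding as well as transcription, so transcription by itself is not settled. A candidate explanation is RNA of the THP1 immunoprecipitates carried into the MOLM13 IgG libraries. At 38 sites strong in THP1 alone, 29 and 28 MOLM13 clusters had a median log2 fold over IgG near the library median. It differed by 0 and −0.063 in the replicates. Only sites with a cluster in both MOLM13 immunoprecipitates entered. Sites with carried-over RNA in the IgG libraries alone are therefore left out, and these medians cannot decide on carry-over. In the 51 genes with at least 20 THP1 and at most 3 MOLM13 clusters, MOLM13 clusters on THP1 peaks lay lower than the others by −0.79 in replicate 1 and −1.0 in replicate 2, but by −0.18 and −0.29 without the 3 genes above. With 10 and 16 clusters left, carry-over in such genes cannot be told apart from no carry-over, and a difference in transcription between the lines stays open.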

How the results depend on the processing

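The settings with a log2 fold of at least 4, IgG for the fold agreement, merged touching peaks and 3' UTR peaks with matching were chosen after the result was seen. Of 74 alternative values of the main results, 39 kept within their bound and 35 moved. The bound was 1.5 times, the replicate spread, the side of the threshold or an interval of counting error across peaks. That interval served for the shares also enriched over IgG and for the fold agreement. It is narrow, so small changes count as moves there. Examples in MOLM13 are 26.0% against 27.3% (Wilson interval 26.5 to 28.1) and r = 0.733 against 0.749. The cause of these moves was not tested, except that a higher threshold or 1 replicate in place of 2 changes the number of peaks by construction. With a log2 fold of at least 4, reproducible peaks numbered 6931 in MOLM13 and 10215 in THP1 over input, 903 and 2587 over IgG, and 3' UTRs held 15.4% and 10.7%. Over IgG in MOLM13 a log2 fold of at least 2 gave 6679 and of at least 1 gave 7354. With a −log10 p of at least 5, 3' UTRs held 21.6% and 16.4%. Among peaks also enriched over IgG in their own replicate they held 31.9% and 18.2%, and with merged touching peaks 15.7% in THP1. Input peaks also enriched over IgG made up 49.9% and 61.2% with a log2 fold over IgG of at least 2, 23.4% and 37.5% with a −log10 p of at least 5, and 26.0% and 44.1% with a reciprocal overlap. Agreement of folds over IgG was r = 0.733 and 0.819 for all clusters and 0.531 and 0.521 at input peaks. Enriched list calls fell from 16 to 9 with matching, and depleted calls from 6 to 3 with 3' UTR peaks and to 2 with matching as well.

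A single replicate gave 4551 to 7165 peaks over IgG in MOLM13 and 8786 to 12038 in THP1, 3' UTR shares of 20.2% to 22.8% and 16.1% to 16.7%, and shares also enriched over IgG of 28.1% to 45% and 43.2% to 59.1%. MOLM13 replicate 1 and THP1 replicate 2 gave the high ends of the peak counts and of the shares also enriched over IgG. The odds ratio for shared targets ran from 18.9 with IgG to 65.9 with 3' UTR peaks. Of the named gene values with IgG in place of input, 96 stayed past the threshold, 33 did not, and CXCL8 in MOLM13 turned to −0.29, the lower of its replicates. CFLAR in MOLM13 had no value over IgG in replicate 1 and is in none of these counts. No paired analysis was possible because the deposited folds already divide each immunoprecipitate by a control and no counts per library were used here. Looser folds over input were not run, since the tables hold only peaks past the threshold, nor were the heptamer search and another annotation order. Read depth per library is unknown, so its effect on the lists is open.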

Other observations

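All tests of explanations in this part, and the genes named, were chosen after the result was seen. The strongest peaks of any region were mostly intronic, and some were shared by the lines. In MOLM13 they included distal introns of MTHFD1L, a mitochondrial folate enzyme gene (log2 folds over input of 9.67 and 9.34, chromosome 6, 150923556 to 150923625), of the coatomer gene COPA (9.60 and 9.20, chromosome 1, 160300313 to 160300340) and of the cleavage stimulation factor gene CSTF3 (9.34 and 9.01, chromosome 11, 33113166 to 33113221). In THP1 the COPA and CSTF3 sites reached 9.51 and 10.08, and 9.63 and 9.35, and distal introns of NLGN1 (9.56 and 10.02) and of the antioxidant regulator gene NFE2L2 (9.83 and 9.47) stood beside them. PVT1, a long noncoding RNA beside MYC, had 52 and 60 enriched peaks over input in MOLM13 and 51 and 46 in THP1.

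NEAT1, the nuclear RNA of paraspeckles, had 7 enriched peaks over input in MOLM13 replicate 1 and 77 in replicate 2, and 19 and 103 in THP1, with 0 enriched over IgG in any of them. The rise was at least 4.32 times that in listed NEAT1 clusters, so more clusters alone do not account for it. Better recovery of nuclear RNA is argued against by intronic peaks, whose ratio of replicate 2 to replicate 1 was at most 0.963, and MALAT1 had 0, 0, 11 and 3 peaks. At least 83.5% of the replicate 2 NEAT1 peaks had a log2 fold under 4, against 37.1% and 33.0% of all peaks, so a small shift of NEAT1 folds across the threshold may account for the difference. What shifted them stays open, and no biological explanation was tested.

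NES, VGF, SOX5, ARHGAP5, MOSMO and NEAT1 had peaks over input in all 4 immunoprecipitates at which IgG was as high as or higher than the immunoprecipitate. In THP1 replicate 2, NES had 10 such peaks with log2 folds up to 6.23 over input and down to −2.73 over IgG, and VGF 5 with up to 7.08 and down to −2.24. Such peaks made up 0.236% and 1.17% of the input peaks in MOLM13 and 0.233% and 0.651% in THP1, but 10.5%, 21.3%, 12.2% and 33.3% of those in 5' UTRs, against 0.0344%, 0.305%, 0.258% and 0.286% in 3' UTRs. RNA of another cell type could bring such peaks. Lists of melanocytic, neural, fibroblast, hepatocyte, erythroid and epithelial markers held 1 of them per library, in SOX5. As SOX5 was among the genes that prompted the test, this hit lends no support to that explanation. The lists did not include SOX10, CSPG4, POU3F2 and SOX11, which had such peaks in THP1. Clusters of the fibroblast list had a log2 fold over IgG of −1 or less in 45% and 66.7% of cases in the THP1 replicates, against 12.3% and 13.2% for all protein-coding genes, but these were 20 and 21 clusters, mostly of COL6A1 and IGFBP7, and COL1A1, COL1A2 and COL3A1 had 0 clusters in any library. In MOLM13 the shares were 17.5% and 50.8% against 7.03% and 35.0%. The melanocytic list gave 8.33% and 65% in MOLM13 and 13.6% and 18.2% in THP1. In THP1, 31 of its 44 clusters and 25 of its 33 clusters were of SOX5. The neural list, with 7, 9, 12 and 15 clusters, gave 28.6% and 66.7%, and 25% and 33.3%. With these few markers, RNA of another cell type cannot be told apart from recovery of these fragments without the antibody's target, and no biological explanation was tested.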
